A study of Homo sapiens with 2 samples.

How the data were processed

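Total RNA of the 2 MCF7 populations was labelled with biotin and hybridised to 1 oligonucleotide array each, per the labels' protocols. The authors deposited log2 expression values, 1 per probe set and array, made with RMA and the affy package per the submitters' processing notes. RMA corrects background, makes the distributions of arrays alike and summarises the probes of a probe set on the log scale. Versions and the background method are not given in the sources used here. The log base was taken from the values, which ran from 0.31 to 15.9, the range of log2 values of a scanner. The sorted values of the arrays lay within 0.076 of each other. The medians were 3.07 in DA and 3.08 in SW, low in the range of values. Values near or below this level are called background in the text, which is an assumption. Of 54675 probe sets 8399 (15.4%) had exactly equal values on both arrays, for a reason not given in the sources used here. Scanner intensities and detection calls were not used here, so no probe set has a measured background, and the precision is limited by the number of arrays.

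Gene names came from the array's platform annotation, in which 42898 probe sets were listed, 41097 with exactly 1 gene and 1801 with several. Symbols were updated through the Entrez identifier to those of the RefSeq annotation of GRCh38.p14 for 41043 of them. Probe sets with several genes or none listed, and 62 control probe sets, were left out of gene results. The probe set with the highest mean of both arrays stood for its gene, which gave 19775 genes. A gene entered the comparisons if the higher of its values was at or above 3.07, the median of all probe-set values on both arrays, which left 12228 genes. No genome was used, and no coordinates are given. Gene order along chromosomes, used only in the closing section, was that of the RefSeq annotation.

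With 1 array per group no test of the difference between groups was made. Genes were counted at a difference of at least 2-fold. Each gene list fixed beforehand was described by its median difference and the percentile of that median among 10000 random lists of the same size, drawn from 20 bins of mean expression. Lists with fewer than 5 members past the filter got no percentile. The percentile describes these arrays and treats genes as independent, which co-regulated genes are not. The genes named in the text follow a rule fixed before the data were examined: CEACAM1, the 15 genes with the largest difference in each direction among those at least 2-fold apart whose probe sets past the filter all had the same direction, and in each list the up to 4 members with the largest difference. Other members named in lists (MKI67, CCNA2, RRM2, CSN2, ID3, TAGLN, GATA3 and CEACAM genes) were added after their values were seen. Of 813 genes at least 2-fold apart 66 had probe sets that did not all share a direction.

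Alternatives fixed beforehand were the mean of all probe sets of a gene, leaving out probe sets whose identifiers mark possible cross-hybridisation, loess centring (span 0.3) and median centring, no filter or a filter at the 75th percentile (6.97), thresholds of 1.5-fold and 3-fold, and an offset of 32 on the linear scale. Centring on the 18 hybridisation control probe sets, bacterial and phage transcripts added to the hybridisation mix, was chosen after seeing the data. The calculations were tested on simulated data with 12228 genes, 200 of them changed 4-fold at a noise SD of 0.2, and recovered 200 with 0 false calls. Of 200 unchanged simulated lists 4% fell outside the central 95%, and all of 50 lists of 20 genes shifted by 0.3 lay above it. The simulation checks the calculations only. Its changed genes lay far from the 2-fold threshold and its genes were independent. It therefore does not gauge how often calls or lists in the data are wrong. The interval of the cell cycle median in the closing section is a bootstrap over its 30 members with 10000 draws. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.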

Results

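Gene expression was measured in MCF7 cells, a human mammary adenocarcinoma line of luminal type that grows as epithelium, after 4 days of growth in Matrigel, a basement membrane gel in which the cells form acini. The cells carried a transfected short-tail isoform of CEACAM1, a cell adhesion molecule of the carcinoembryonic antigen family. One population (SW) expressed the wild-type isoform. The other (DA), titled as the control, expressed a mutant in which a threonine and a serine of the cytoplasmic tail were replaced by alanine. The comparison addresses which genes differ between acini that carry the wild-type tail and acini that carry the mutant tail, in a model used to study lumen formation. Each group consisted of 1 oligonucleotide array with 54675 probe sets. No difference below therefore has a replicate check, no p-value is given, and the culture and the array cannot be separated from the transgene. Whether each population was a clone or a pool of transfected cells is not given in the sources used here, so a difference between clones is equally not separated from it. The CEACAM1 signal was 4.23-fold lower in SW, so the level of the transgene cannot be separated from the mutated tail either. The spread available is the SD between probe sets of the same gene, with a median of 0.13 and a 90th percentile of 0.44 on the log2 scale over 5962 genes with at least 2 probe sets past the expression filter. It covers probe error within these arrays only. Differences are SW minus DA in log2 units throughout, and a fold is the same difference on the linear scale.

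CEACAM1, the transfected gene, was detected in both populations and was 4.23-fold lower in SW, at 10.46 against 12.54 log2 units. Its other probe sets past the filter gave differences of -2.26 and -2.16, and its remaining pair stayed near 1.9 log2 units on both arrays, below the filter. All CEACAM1 probe sets past the filter have identifiers that mark possible cross-hybridisation, so without such probe sets the gene does not pass the filter. Its relatives differed in the opposite direction. CEACAM6, a glycolipid-anchored adhesion molecule, was at 9.40 log2 units in DA and 12.40 in SW, a difference of 3.00, and its other probe set gave 9.89-fold. CEACAM5, the carcinoembryonic antigen itself, was 10.1-fold higher in SW, at 10.69 against 7.35, with a further probe set below the filter on both arrays. CEACAM7 was 12.9-fold higher by its brightest probe set, whereas its other probe sets gave differences of 1.38 and 0.036. Its DA value of 3.52 was close to the filter, and with the offset of 32 the difference was 2.05. CEACAM3 was at 3.17 on both arrays, and CEACAM4, CEACAM8, CEACAM19 and CEACAM21 were below the filter. The median of the 5 family members past the filter was 3.00, above all of 10000 random gene lists of matched brightness. Without the filter, which adds the members at background, the median of the CEACAM family was -0.00057 relative to the median of all genes, 0.0037. It was at percentile 36.6 and no longer stood apart. Both populations carry CEACAM1, and whether any of its probes covers the mutated codons was not examined. CEACAM1 therefore does not check which array carries which transgene.

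**Figure D1:**
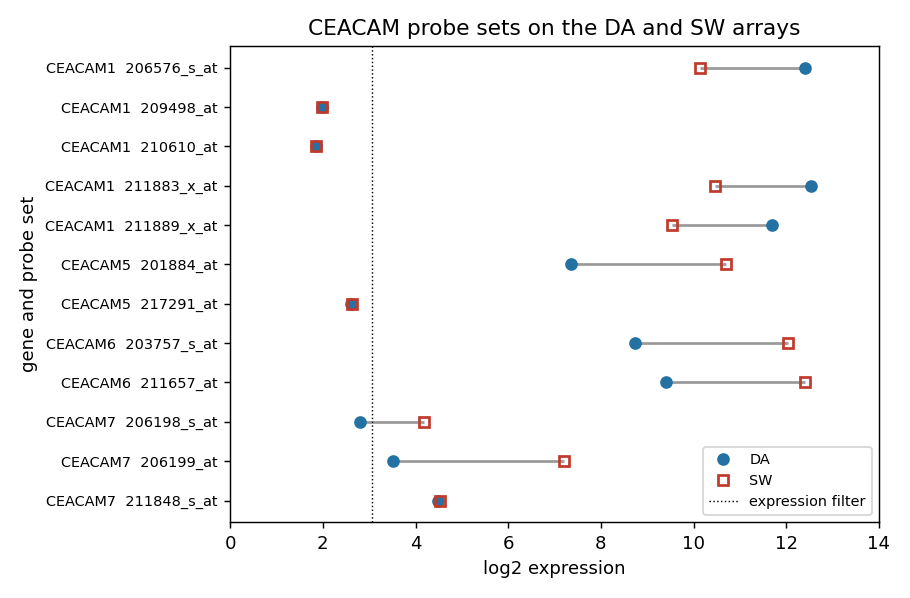
Log2 expression of each CEACAM1, CEACAM5, CEACAM6 and CEACAM7 probe set on the DA array (filled circles) and the SW array (open squares), with the expression filter as a dotted line. CEACAM1 probe sets past the filter had differences of -2.08 to -2.26, and the 2 CEACAM6 probe sets had 3.00 and 3.31.

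Of 12228 genes past the expression filter, 406 were at least 2-fold higher in SW and 407 at least 2-fold lower. At least 10-fold differences were found for 43 genes in the direction of SW and 36 in the direction of DA. Centring on the hybridisation controls, which lay 0.23 higher on the SW array, gave 278 higher and 620 lower, so the even split depends on the scaling. The poly-A controls, added before labelling, had a median difference of only 0.0040, with 14 above 0 and 10 equal. Centring on the poly-A controls was not run. With the mean of all probe sets per gene, the counts were 267 and 269. A second probe set past the filter was present for 399 of the genes at least 2-fold apart and had the same direction in 365 of them, at least 2-fold in 229. The other 414 had no second probe set past the filter.

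Among the genes higher in SW, TCN1, a secreted vitamin B12 binding protein, stood apart, with 12.52 log2 units in SW against 2.07 in DA, a difference of 10.45. The long noncoding RNA TMEM132D-AS1 differed by 6.85, at 5.10 in DA and 11.96 in SW. CA2, a cytosolic carbonic anhydrase, differed by 6.83. SDC2, a heparan sulfate proteoglycan, differed by 6.80, with 2.38 to 6.80 over 3 probe sets, and ID4, an inhibitor of helix-loop-helix transcription factors, by 6.70, with 0.53 to 6.70 over 4 probe sets. IMMP2L, a mitochondrial inner membrane peptidase, differed by 6.02, SLITRK6, a transmembrane protein, by 5.72, COX7B2, a cytochrome oxidase subunit, by 5.50, and HS6ST2, which sulfates heparan sulfate, by 5.46. CPS1, the first enzyme of the urea cycle, differed by 5.44, and ADD3, an adducin that joins actin to spectrin, by 5.16 to 6.12 over its 4 probe sets. SLC18B1 differed by 4.78, FIGN, a microtubule-severing ATPase, by 4.77, SPART by 4.62 and FXYD5, a regulator of the sodium pump, by 4.58. With the mean of all probe sets, ID4 differed by 2.01, IMMP2L by 3.01, FIGN by 2.79 and SPART by 1.16. For 8 of these 15 genes the DA value lay below the filter, and their fold rests on a background value. The DA values of SPART (3.08), COX7B2 (3.32) and SLITRK6 (3.42) were close above the filter, so their folds also rest on values near background. After 32 was added to both linear values, the difference of TCN1 was 7.35 and that of SLC18B1 was 2.05.

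Among the genes lower in SW, GPX3, a secreted glutathione peroxidase, was at 1.86 log2 units in SW and 9.04 in DA, a difference of -7.18. BTBD6 differed by -6.85 and EFHD1, a calcium-binding protein of mitochondria, by -6.40. NPNT, an integrin ligand of basement membranes, differed by -5.79, SERPINA3, a secreted antiprotease, by -5.04, CRISP3 by -4.57, and EGF, the epidermal growth factor, by -4.56. RUNX2, a transcription factor of bone formation, differed by -5.30 and CRABP2, a retinoic acid binding protein, was at 6.90 log2 units in DA and 2.90 in SW. The adhesion molecule AMIGO2 differed by -4.89, MICB, a ligand of a natural killer cell receptor, by -4.47, the interferon-inducible IFITM1 by -4.31 and VTCN1, an inhibitory B7 molecule, by -4.26. BRINP2 differed by -4.73 and LINC00052 by -4.51. For 5 of the 15 the SW value lay below the filter. With the mean of all probe sets, NPNT differed by -3.20 and RUNX2 by -0.88, which is less than 2-fold. All 30 genes named by size were at least 2-fold apart with the offset of 32.

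**Figure D2:**
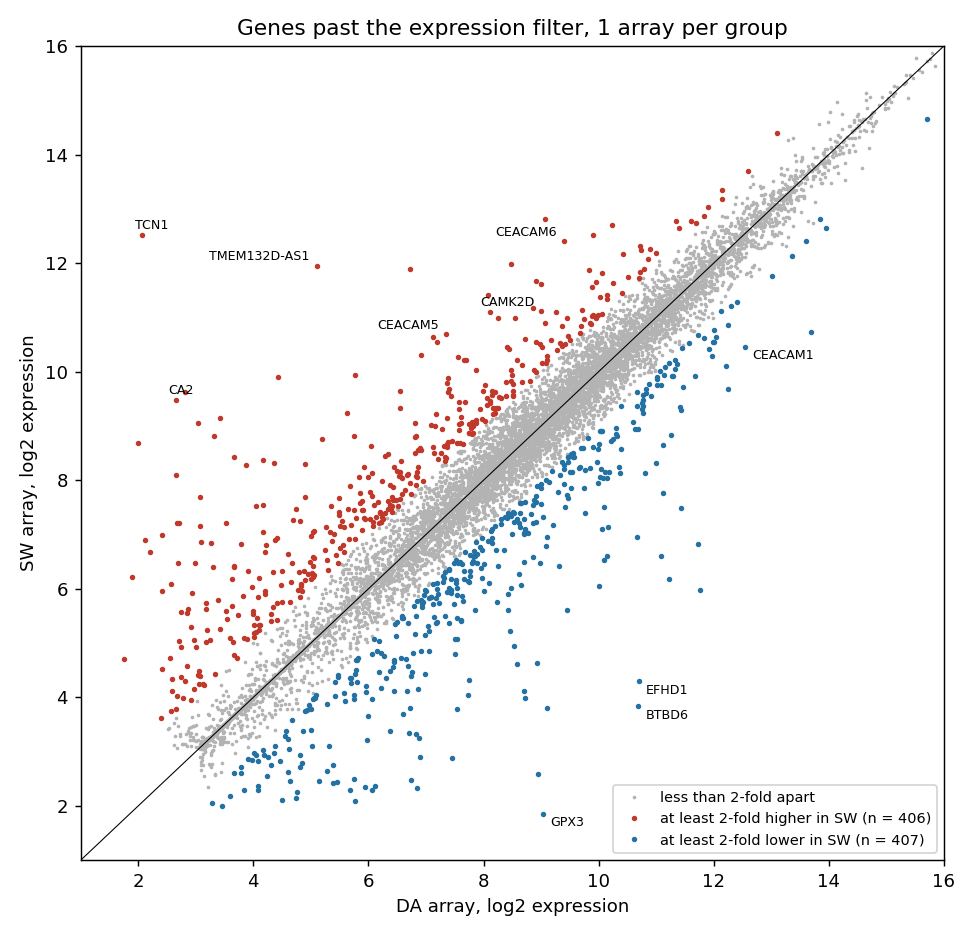
Log2 expression of 12228 genes past the filter on the DA array (horizontal) and the SW array (vertical). Red points are the 406 genes at least 2-fold higher in SW, blue points the 407 at least 2-fold lower, the line marks equality, and TCN1 is the gene farthest above it.

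Of the 28 gene lists fixed beforehand, 25 had enough members for a comparison with random lists, and 12 of these had medians outside the central 95% of random lists, where 1.25 would be so by chance if lists were independent. The list medians are relative to the median of all genes past the filter, which was 0. Under an alternative they are relative to the median of all genes in that setting. It was 0.0037 without the filter and 0.00088 with the mean of probe sets. On the scale of the hybridisation controls all medians would be 0.23 lower, and among these 12 the luminal, cholesterol, p53 and immediate early medians would lie below 0.

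Cell cycle genes were lower in SW by a small amount. Of 30 members 28 were below 0, none was 2-fold apart, and the median of -0.30 was below all random lists. AURKB and AURKA, kinases of mitosis, differed by -0.73 and -0.71, although another probe set of each was equal on both arrays. UBE2C, a ubiquitin-conjugating enzyme of mitosis, differed by -0.64 and TK1, thymidine kinase, by -0.60. The proliferation marker MKI67 differed by -0.41. CCNA2 at 0.40 and RRM2 at 0.032 had the opposite sign.

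Genes of transforming growth factor and bone morphogenetic protein signalling were higher in SW, with a median of 0.47 over 15 members at the 99.99th percentile, of which 13 were above 0 and 2 at least 2-fold higher. The median of TGF-beta and BMP targets was smaller with the mean of probe sets, at 0.30, and without the filter, at 0.15, but above random lists in both. Among the inhibitors of helix-loop-helix factors, ID4 was at 6.70 from a DA value below the filter, ID2 at 1.37, ID1 at 0.91 and ID3 at 0.25, and SKIL, a repressor of SMAD proteins, was at 0.86. The list of calmodulin-dependent kinases and calcium-binding proteins had a median of 0.32 over 16 members, also at the 99.99th percentile, with 4 at least 2-fold higher and none lower. CAMK2D, the delta subunit of calcium/calmodulin-dependent kinase II, was 4.31-fold higher in SW, at 11.11 against 9.01 log2 units, with 1.84 to 2.67 over 4 probe sets. S100P differed by 2.61, CALML5 by 1.55 and S100A6 by 1.11, the last with another probe set at 0. Without the filter the median of calmodulin-dependent kinases and calcium binding was 0.0053 at percentile 96.6, inside the central 95%.

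Lists of mammary markers also lay above random lists, each under some settings only. The luminal list had a median of 0.17 over 14 members at the 98.9th percentile, with ELF5, a factor of secretory differentiation, at 1.55, AGR2 at 0.94, ESR1, the oestrogen receptor, at 0.72 and SPDEF at 0.62. ESR1 ranged from -0.0046 to 0.72 over 7 probe sets and differed by 0.26 with the mean of all probe sets. Of the members 12 were above 0 and 2 below, among them GATA3 at -0.59, with -1.03 to -0.59 over 3 probe sets. The luminal mammary markers were inside the central 95% with the mean of probe sets (percentile 96.0) and without possibly cross-hybridising probe sets (percentile 93.8). Milk and secretory products had a median of 0.53 over 7 members at the 99.9th percentile. Here ELF5 was joined by AZGP1 at 1.24, PRLR, the prolactin receptor, at 0.69 and MUC1 at 0.53, whereas the casein CSN2 was near background at 3.21 log2 units in DA. Without possibly cross-hybridising probe sets, the median of milk and secretory products was 0.0069 at percentile 81.1, and without the filter it was 0.0053, above random lists but near 0. The basal and myoepithelial list rested on 5 members with a median of 0.87 at the 99.9th percentile, namely EGFR at 1.21, CAV1 at 0.89, ACTA2 at 0.87, ITGB4 at -0.070 and TAGLN, which was equal on both arrays. EGFR and CAV1 were below the filter in DA, and with the offset of 32 they differed by 0.30 and 0.18. Without the filter the median of basal and myoepithelial markers was -0.00099 relative to that of all genes, inside the central 95%.

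Other lists also lay outside the central 95%. Cholesterol synthesis genes had a median of 0.16 over 16 members at the 97.8th percentile, with none 2-fold apart and MSMO1 at 0.60, LSS at 0.47, STARD4 at 0.47 and FDPS at 0.35. Another LSS probe set gave -0.56, and with the mean of probe sets cholesterol synthesis was at percentile 94.9, inside the central 95%. Targets of p53 had a median of 0.21 over 19 members at the 99.5th percentile, with SPATA18 at 1.34, ZMAT3 at 0.92 and TP53INP1 at 0.74, but GDF15, a stress-induced cytokine, at -2.06. Immediate early genes had a median of 0.20 over 20 members at the 99.6th percentile and went both ways, 3 at least 2-fold higher and 3 lower, with FOS at 1.99 and KLF4 at 1.38 against DUSP5 at -1.71 and DUSP6 at -1.50, the last with another probe set at 0.0010 and a difference of -0.70 with the offset of 32. The immediate early genes were inside the central 95% without possibly cross-hybridising probe sets (percentile 93.3) and without the filter. Actin cytoskeleton genes had a median of -0.12 over 19 members at the 2.5th percentile but a mean of 0.020. LIMA1, an actin-bundling protein, was at 2.14 by its brightest probe set and 0.013 by another, RDX at 0.94 and TPM4 at 0.71, against CORO1C, a coronin, at -1.11. Without possibly cross-hybridising probe sets the actin cytoskeleton list was at percentile 12.7. Notch and Wnt genes had a median of -0.078 over 19 members at the 1.8th percentile, with a mean of 0.061. HEY2, a Notch target, was 12.1-fold higher in SW by both probe sets, and DKK1, a secreted Wnt inhibitor, differed by 1.74. The ligand JAG1 differed by -2.06, with another probe set at 0, and RNF43 by -1.51. With the mean of all probe sets, without the filter or with the stricter filter, this list was no longer apart from random lists.

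**Figure D3:**
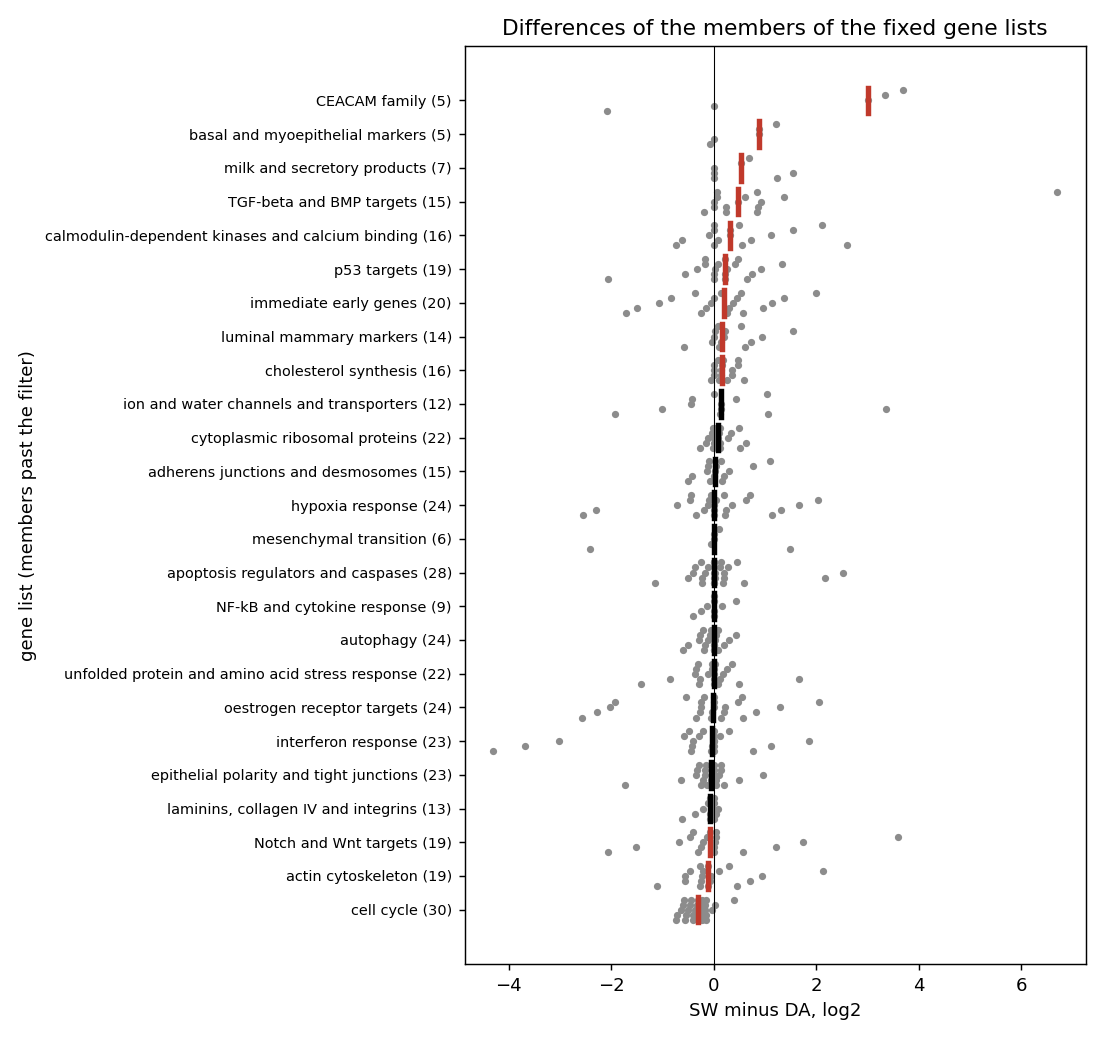
Differences (SW minus DA, log2) of the members of each fixed list past the filter (grey points) with the list median as a bar, red where it lies outside the central 95% of random lists of matched brightness. The number of members is in brackets, and cell cycle genes form the lowest list with a median of -0.30.

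The remaining lists had medians inside the central 95%. Apoptosis regulators and caspases had a median of 0.00078 over 28 members (percentile 69.8) and 25 members within 2-fold. The exceptions were CASP4, an inflammatory caspase, at 2.52, BIK, a BH3-only protein, at 2.17, and BCL2L11, another BH3-only protein, at -1.15 with another probe set at 0, while XIAP was at 0.59. Autophagy genes had all 24 members within 2-fold and a median of 0 (percentile 43.4), with WIPI2 at -0.60, ATG5 at -0.51, ATG10 at 0.44 and GABARAPL2 at 0.29. Polarity and tight junction genes had 22 of 23 members within 2-fold and a median of -0.046 (percentile 12.0). CGN, the tight junction protein cingulin, was at -1.73, DLG1 at 0.97, LLGL1 at -0.63 and MARVELD3 at 0.50. Adherens junction and desmosome genes had a median of 0.020 over 15 members (percentile 79.3), with PERP at 1.10 (0.0070 to 1.52 over 4 probe sets), DSP, desmoplakin, at 0.77, DSC2 at -0.51 and NECTIN2 at -0.42. Laminins, collagen IV and integrins had all 13 members within 2-fold and a median of -0.063 (percentile 4.9), with ITGA6 at -0.62, LAMA5 at -0.37, LAMB2 at -0.21 and ITGA2 at -0.11. Of the mesenchymal genes only 6 of 20 passed the filter, with a median of 0.0024 (percentile 65.0) and a mean of -0.15. FN1, fibronectin, was 5.36-fold lower in SW, LOX, below the filter in DA, differed by 1.49 (0.40 with the offset of 32), ITGA5 by 0.095 and TGFB1 by -0.062.

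Oestrogen receptor targets had 18 of 24 members within 2-fold and a median of -0.014 (percentile 27.4), with CA12 at -2.56, SERPINA1 at -2.28, PDZK1 at -2.03 and IGFBP5 at 2.05. Interferon-responsive genes had a median of -0.042 over 23 members (percentile 2.74), and a few members lay far apart. IFITM1 was 19.8-fold lower in SW and ISG15 8.10-fold. BST2, below the filter in SW, differed by -3.67, and by -1.25 with the offset of 32, while IFIH1, a sensor of double-stranded RNA, was at 1.86 by its brightest probe set and 0.0078 by the other. Hypoxia-responsive genes had a median of 0.011 over 24 members (percentile 79.6), with 4 at least 2-fold higher and 2 lower, among them NDRG1 at 2.04, DDIT4 at 1.66, ENO2 at -2.56 and EGLN3 at -2.29. Unfolded protein and amino acid stress genes had a median of 0 over 22 members (percentile 46.1), with DDIT4 again, SLC7A11, the cystine transporter, at -1.41, CEBPB at -0.85 and SLC7A5 at 0.49. Genes of NF-kB and cytokine signalling had all 9 members within 2-fold and a median of 0 (percentile 31.3), with NFKBIA at 0.44, IRF1 at -0.40, NFKB2 at -0.25 and NFKB1 at 0.16. Ion and water channels and transporters had a median of 0.14 over 12 members (percentile 96.3), with CLIC3, a chloride intracellular channel protein, at 3.36, KCNK5 at -1.93, CLCN3 at 1.07 and AQP3 at 1.05. Ribosomal proteins had all 22 members within 2-fold and a median of 0.074 (percentile 96.0), with RPS19 at 0.63, RPL18 at 0.51, RPL37 at 0.48 and RPS16 at 0.34.

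Some list members named above as at least 2-fold apart were not so under an alternative. With the mean of all probe sets this held for BCL2L11, PERP, ELF5, IFIH1, GDF15, SPATA18, S100A6, CORO1C, DUSP6, JAG1, AQP3 and CLCN3, and with the offset of 32 for LOX, EGFR, DUSP6 and KCNK5.

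Markers of other cell types did not differ by 2-fold between the arrays in the brightest probe set of any member past the filter. Of 10 fibroblast markers 4 passed it, with a median of 0.059, COL1A1 at 8.92 and 9.04 log2 units in DA and SW, COL3A1 at 0.28 in difference, LUM at 0.0055 and POSTN equal on both arrays. Of the endothelial markers EGFL7 was at -0.57, PECAM1 at 0.0050 and CLDN5 at 0.00059, and ERG was equal on both arrays by its brightest probe set and 1.15 by another. The median of these 4 was 0.00030. The leukocyte markers PTPRC and CD3D lay between 3.08 and 3.15, at the filter, with a median difference of 0.0047. The ratio of 3' to 5' signal, a measure of RNA integrity, had log2 values of 1.28 in DA and 1.51 in SW for ACTB, 0.16 and 0.057 for GAPDH, and 1.86 and 1.68 for STAT1. It was thus higher in SW for ACTB, by 0.23, and lower in SW for GAPDH, by 0.10, and for STAT1, by 0.18.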

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

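Both results here are signals in probe sets that the gene comparisons leave out. Among 4947 probe sets past the filter that have no single named gene, 121 were at least 2-fold higher in SW and 83 at least 2-fold lower. The highest difference of a single probe set was 5.34, with 3.91 log2 units in DA and 9.25 in SW, and the lowest was -4.71, with 8.96 and 4.25. The 18 hybridisation control probe sets were higher on the SW array by a median of 0.23, with 17 above 0 and 1 equal, although the same amount is normally added to each array. The 24 poly-A control probe sets, transcripts added before labelling, had a median of 0.0040, with 14 above 0 and 10 equal.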

How the results depend on the processing

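No difference has a replicate behind it, so the alternatives show only dependence on processing, and leaving out arrays was not possible. Centring on the hybridisation controls was chosen after seeing the data, the other alternatives before. The counts of genes at least 2-fold higher in SW and at least 2-fold lower in SW were 406 and 407. They were 267 and 269 with the mean of probe sets, 933 and 924 at 1.5-fold, 180 and 172 at 3-fold, 272 and 264 with the offset of 32, which shrinks dim genes by construction, and 278 and 620 with hybridisation control centring. The remaining settings kept each count within 1.5 times. The CEACAM1 transgene differed by -2.08, by -2.26 in another probe set and by -2.31 with hybridisation control centring, whereas its 2 probe sets below the filter gave 0.010 and 0.0066. Leaving out possibly cross-hybridising probe sets would keep only these 2 for CEACAM1. Of the 12 lists apart from random lists, the cell cycle, TGF-beta and BMP, and p53 lists stayed apart under each alternative run on lists, though the median of TGF-beta and BMP targets fell from 0.47 to 0.15 without the filter and 0.30 with the mean of probe sets. Median centring shifts all genes alike, so it cannot move a percentile. On the scale of the hybridisation controls the p53 median of 0.21 would be -0.021. Medians without the filter, which adds genes at background, are relative to that of all genes, 0.0037. The CEACAM family was then at -0.00057, basal and myoepithelial markers at -0.00099 and Notch and Wnt targets at -0.0032. Calmodulin-dependent kinases and calcium binding were at 0.0053, as were immediate early genes. None of these lists was apart from random lists. The median of milk and secretory products fell from 0.53 to 0.0053 but stayed apart. Without possibly cross-hybridising probe sets, 4 lists were no longer apart: luminal mammary markers (0.20), milk and secretory products (0.0069), actin cytoskeleton (-0.029) and immediate early genes (0.078). With the mean of probe sets the same held for luminal mammary markers (0.089), cholesterol synthesis (0.099) and Notch and Wnt targets (-0.038), and with the 75th percentile filter the Notch and Wnt median was 0.020, above 0. The cause was not tested. The interferon list (-0.13, mean of probe sets) and ribosomal proteins (0.074, 75th percentile filter) lay outside the central 95% only there. Of 768 values of the 135 named genes under alternatives, 274 moved by more than the median SD between probe sets of a gene. Of these, 135 came from hybridisation control centring, whose shift exceeds that SD for every gene by construction. No named gene at least 2-fold apart changed sign. The offset keeps the sign by construction, and the shifts by centring were smaller than 2-fold. Only the mean of probe sets and leaving out possibly cross-hybridising probe sets could thus have changed a sign. The genes named by size were also chosen for probe sets past the filter that share a direction. Dim genes, near background on one array, have the least certain folds.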

Other observations

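The gene families here, the windows along chromosomes, and the tests on cross-hybridisation, exchanged labels, the cell cycle list and genes without a second probe set were chosen after the result was seen, and the test on wide neighbourhoods after the window means but before its own value. Some families outside the fixed lists lay to one side of the median of all genes. Because they were chosen after their values were seen, their percentiles only describe them and give no support. Metallothioneins, small metal-binding proteins, were higher in SW, with a median of 0.66 over 7 members (99.9th percentile of random lists), among them MT1X at 1.20, MT2A at 1.14 and MT1H at 1.08. Of 10 beta protocadherins, adhesion molecules encoded by a cluster of neighbouring genes, all were above 0, with a median of 0.59, PCDHB4 at 2.05 and PCDHB8 at 2.03. With the offset of 32 these 2 differed by 0.97 and 1.22, and the other PCDHB4 probe set was at 0.83. Members of both families are similar in sequence, so which of them a probe set measures is uncertain. ADP-ribosyltransferases had a median of 0.37 over 11 members (99.7th percentile), with PARP9 at 2.19 (1.62 with the offset) and PARP14 at 2.01 (1.35) by its brightest probe set and 0.022 by another, while PARP1 was at -0.10. Enzymes that start mucin-type O-glycans had 3 of 12 members at least 2-fold higher, GALNT12 at 2.62, GALNT10 at 1.16 and GALNT7 at 1.04, with a median of 0.071 (percentile 91.3) that would lie below 0 on the scale of the hybridisation controls. On that scale GALNT10 and GALNT7 would be less than 2-fold apart.

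Coronins, actin-binding proteins, had 5 of 5 members below 0, with a median of -1.07, CORO1C at -1.11 and CORO2A at -1.10. With the offset of 32 only CORO1C stayed at least 2-fold apart, at -1.09, against -0.44 for CORO2A and -0.78 for CORO1A. Lysyl oxidases, which cross-link collagen, had LOXL1 at -3.25, LOXL3 at -1.63 and LOXL2 at -1.41, against LOX at 1.49. The dimmer values of LOXL1, LOXL2 and LOX lay below the filter, and with the offset of 32 they differed by -1.19, -0.27 and 0.40. The aldo-keto reductases AKR1C1 and AKR1C2, which share much of their sequence, were at -2.20 and -2.34, whereas AKR1C3 was at 0.18. Of 2 cancer-testis antigens of the MAGEA group past the filter, MAGEA12 was at 3.57 and MAGEA6 at 0.011.

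CEACAM1 was lower in SW while CEACAM5, CEACAM6 and CEACAM7 were higher. Cross-hybridisation of CEACAM1 RNA to its paralogs predicts that they follow CEACAM1. Over the brightest probe set of each gene their lowest difference was 3.00, in the opposite direction. The other CEACAM7 probe sets, at 1.38 and 0.036, were not lower either. These directions are part of the pattern itself, so they are no separate test. Cross-hybridisation among CEACAM5, CEACAM6 and CEACAM7, or of their RNA to CEACAM1 probe sets, was not tested. A copy number change of the surrounding segment predicts neighbours at least 2-fold higher, but the 20 nearest measured genes outside the family had a median of 0.11 and an upper quartile of 0.62. Of the 12 brighter ones, past the 75th percentile filter, 10 were above 0, with a median of 0.34 and a highest value of 0.92, so a smaller gain of the segment could at most have contributed to differences of 3.00 and more, while a gain confined to CEACAM genes stays open. Exchanged array labels cannot be told apart from the labelled order, because both populations carry CEACAM1, so its difference of -2.08 has no sign fixed by the design. An effect of the mutated tail or of transgene level is also untested.

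The lower cell cycle list had a median of -0.25 with the mean of all probe sets, below all random lists, which argues against the choice of probe set. An intensity trend predicts a like shift in other genes of the same brightness. Random lists matched on brightness had a median of 0, with a central 95% reaching down to -0.11. The cell cycle list was at -0.30 (bootstrap 95% interval -0.43 to -0.23). Genes of the same brightness were thus not shifted alike. The list was set apart by this same comparison, so it is no separate test of a trend. A stricter bound, the lowest of the random lists at -0.23, was tried first and the interval just reached it; it was replaced after that was seen, because it depends on how many lists are drawn. A difference in growth between the populations may account for it, but culture density and harvest are equally open with 1 culture per group.

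Of the genes at least 2-fold apart, 399 had a second probe set, which shared the direction in 91.5% (exact 95% interval 88.3% to 94.0%). A difference of any size counted, even a nearly flat one, such as 0.0078 for IFIH1 and 0.0096 for SPATA18. That share therefore does not decide whether the differences are errors of single probe sets. In 57.4% the second probe set was also at least 2-fold apart in the same direction, which argues against such errors for these genes. For the 414 without a second probe set, errors of single probe sets cannot be told apart from real differences. A candidate explanation is that the populations differ in copy number of chromosome segments. Adjacent measured genes, in the gene order of GRCh38.p14, that were both 2-fold apart shared a direction in 78 pairs, against a median of 26 and a highest count of 44 in 1000 shuffled orders, and 18.1% of the genes 2-fold apart had such a neighbour (shuffled median 6.40%). This share lay below the 20% set beforehand as evidence against copy number as the main cause, but its exact 95% interval of 15.5% to 20.9% spans that bound, and requiring the whole interval to lie below it was decided after the share was seen. Of 716 genes 2-fold apart, 28.2% (24.9% to 31.7%) lay among 25 less different genes on each side whose mean was shifted in the same direction beyond shuffled orders, against a median of 2.37% and a highest share of 4.89% when the neighbours were shuffled. Still, a part played by copy number cannot be told apart from shared local regulation.

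In windows of 51 consecutive measured genes, with each difference limited to between -1 and 1, the lowest mean was -0.57, from PLEKHG4B to LINC02109, and the highest was 0.40, from BABAM2 to LRPPRC. The bounds from 200 shuffled orders were -0.23 and 0.24, and 1015 of 11049 overlapping windows lay outside them.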
